A study of Mus musculus with 24 samples.

How the data were processed

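Gene expression was measured with 24 one-colour Agilent mouse arrays, 8 on each of 3 slides, in the spleen of BALB.K and B10.BR mice that were irradiated 24 hours earlier or were left at rest. Per the labels, each of the 3 replicates of a group is RNA pooled from 3 mice, extracted from homogenised splenocytes with TRIzol and an RNeasy column, checked on a Bioanalyzer and labelled with Cy3. The spread between replicates is therefore that between pools. The sex of the mice is not given in the sources used here.

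Per the file headers, the scanner files hold intensity in arbitrary units, extracted with Agilent Feature Extraction 10.5.1.1, and their processed signal is background-subtracted and detrended on each array. The deposited matrix holds log2 values that the authors centred per probe, and the labels do not state their normalization. Its columns had medians of -0.12 to 0.18. In the BALB.K columns each probe had a median of 0 over the 12 arrays, whereas the baseline of the 12 B10.BR columns stays unknown, so that this matrix was used within a strain only, as an alternative.

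The processed signal was taken as log2 and the array's 75th percentile over non-control probes was subtracted. Spots marked as outliers by the extraction software were left out, and replicate spots of a probe were averaged. A probe was kept if it was well above background, as the software marks it, on all 3 arrays of at least 1 group, which left 42307 of 55681 probes. Names came from the platform's own columns, matched to RefSeq (GRCm38.p6) by accession for 26413 probes, by symbol for 3859 and by synonym for 735, and 24674 probes kept the file's name. The probe with the highest mean stood for each gene, which gave 29521 features, 19815 of them with a RefSeq symbol. Other probes of a gene are spoken of where they went the other way. No spot was saturated, and no 2 arrays held the same values.

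A linear model with a mean per group was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment per comparison at 0.05, two-sided. Files were read with data.table version 1.17.8. There were 13 comparisons: each dose against 0 within its strain, successive doses, the strains without irradiation, and the difference between the strains' changes at 300 cGy and at the highest doses. Lists of genes, 25 in all, were tested with camera (preset correlation 0.01) with adjustment over the 25 lists of a comparison. Of the list tests 194 passed, 72 with a correlation estimated from the data and 192 with fry, which tests whether a list's genes move on balance in 1 direction.

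The lists were p53 targets, proliferation, DNA repair, apoptosis regulators, erythroid, B cell, plasma cell, T cell, regulatory T cell, NK and cytotoxic cell, macrophage, neutrophil and granulocyte precursor, dendritic cell, megakaryocyte and platelet, stroma and endothelium, inflammatory cytokine and chemokine, interferon response, antigen presentation, hematopoietic growth factor, oxidative stress response, immediate early and heat shock, exocrine pancreas, adipocyte, mast cell and basophil and sex-linked. Other spleen cells express marker genes of a cell type too, and 9 of the lists share genes with another.

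The design, the lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall that have a symbol, lie well above background on all arrays of a group compared and have all arrays of one group above all of the other (a condition dropped for the differences between strains). It adds up to 3 called members with the largest change of each list that passed, the sex-linked list in the unirradiated comparison, and, called or not, Cdkn1a, Mdm2, Ccng1, Bax, Trp53, Mki67, Prkdc, Cdkn2a, Cd3e, S100a8, Cd68 and Pf4. The text gives part of the genes so chosen, and some that the rule always names are not reported here. The islet genes Ins1, Ins2, Sst, Iapp, Pyy and Chga were chosen later, for a test in the closing section.

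Tested on simulated data for BALB.K at 300 cGy against 0, with 29521 features and the spread of the arrays, the steps recovered 58 of 100 genes set to a log2 change of 1 and 88 of 100 set to 2. Of the calls in that test 5.81% were of unchanged genes. Fewer genes were changed there than the 13812 called in the data, so that these shares need not carry over. Replicate numbers were checked for pairing by the correlation of residuals, which was above 0.1 in every pair only for B10.BR at 900 against 500 cGy (0.21, 0.12 and 0.24), so that no pairing entered the fit.

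The alternatives were quantile normalization, median scaling, scaling on 10 spike-in probes, normexp background correction (offset 50), no filter or a stricter filter on dim probes, marked spots kept, the mean of a gene's probes, a fit on only the arrays compared, an intensity trend with robust moderation, array weights, the replicate number as a block, slide as a fixed or random block (correlation 0.140), the deposited matrix, and leaving out each array. Chosen after the data were seen were the mean level of the exocrine list or Y-linked signal as a covariate, BALB.K arrays with or without Y-linked signal alone, and comparisons within 1 slide. All 24 arrays were used.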

Results

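Spleen gene expression was measured 24 hours after total body irradiation in 2 inbred mouse strains, BALB.K and B10.BR, with 24 one-colour Agilent arrays. Unirradiated mice of each strain (0 cGy) were set against 300, 400 and 800 cGy in BALB.K and against 300, 500 and 900 cGy in B10.BR. Each of the 8 groups had 3 arrays, each of RNA pooled from 3 mice. The series names 800 and 900 cGy myeloablative, which means that they ablate the bone marrow. On each array 67.0% to 76.9% of 55681 probes were well above background, and the 75th percentile of the signal lay between 830.3 and 1235 intensity units. The number of arrays limits the precision.

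Values are log2 changes ± the standard error of the limma fit, with 3 arrays against 3, and a gene is said to have risen or fallen only where its adjusted p passed. A gene given for its large rise or fall within a comparison of doses or strains had all 3 arrays of one group above all 3 of the other. Where a probe was above background on no array of one group, the change is given as a bound, computed with that group's values raised to the lowest level still above background on its arrays. A gene list was tested against all other genes with camera, and its median is that of its genes' log2 changes. Shifts in the mix of spleen cells were not told apart from changes within cells. Counts adjusted over the list alone are given where they differ from those over all genes. The arrays lay on 3 slides. Slide 1 held B10.BR at 0, 300 and, for 2 arrays, 500 cGy. Slide 2 held the third 500 cGy array, B10.BR at 900 cGy, BALB.K at 0 and 1 array at 300 cGy, and slide 3 the other BALB.K arrays. No slide held both groups for BALB.K at 400 or 800 cGy against 0, B10.BR at 900 cGy against 0 or the unirradiated strains. Medians with slide as a block of the fit stand after the words with the block. A factor per array moves every gene alike, so that differences from the median of all genes are equal under percentile, median and spike-in scaling. The exocrine level as a covariate removes the change of the exocrine list, and is not given for its genes.

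Genes of other tissues and of the sex chromosomes differed between arrays of 1 group. The 19 genes of the exocrine pancreas list, mostly digestive enzymes made by acinar cells, held 0.00526% to 0.131% of the summed signal in unirradiated BALB.K and 0.0321% to 1.0%, 0.00299% to 0.232% and 0.201% to 0.808% at 300, 400 and 800 cGy. In B10.BR their share was 0.000864% to 0.00362% at 0, 0.0582% to 0.718% at 300, 0.00179% to 0.198% at 500 and 0.570% to 0.807% at 900 cGy. Ddx3y, carried on the Y chromosome, was well above background on all 12 B10.BR arrays, on replicate 1 of BALB.K at 0, 300 and 400 cGy and on the 3 BALB.K arrays at 800 cGy. On the 6 other BALB.K arrays it was at -8.0 log2 or lower, and Xist, which is transcribed from an inactive X chromosome, was between -3.31 and -2.08 on those 6.

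**Figure D1:**
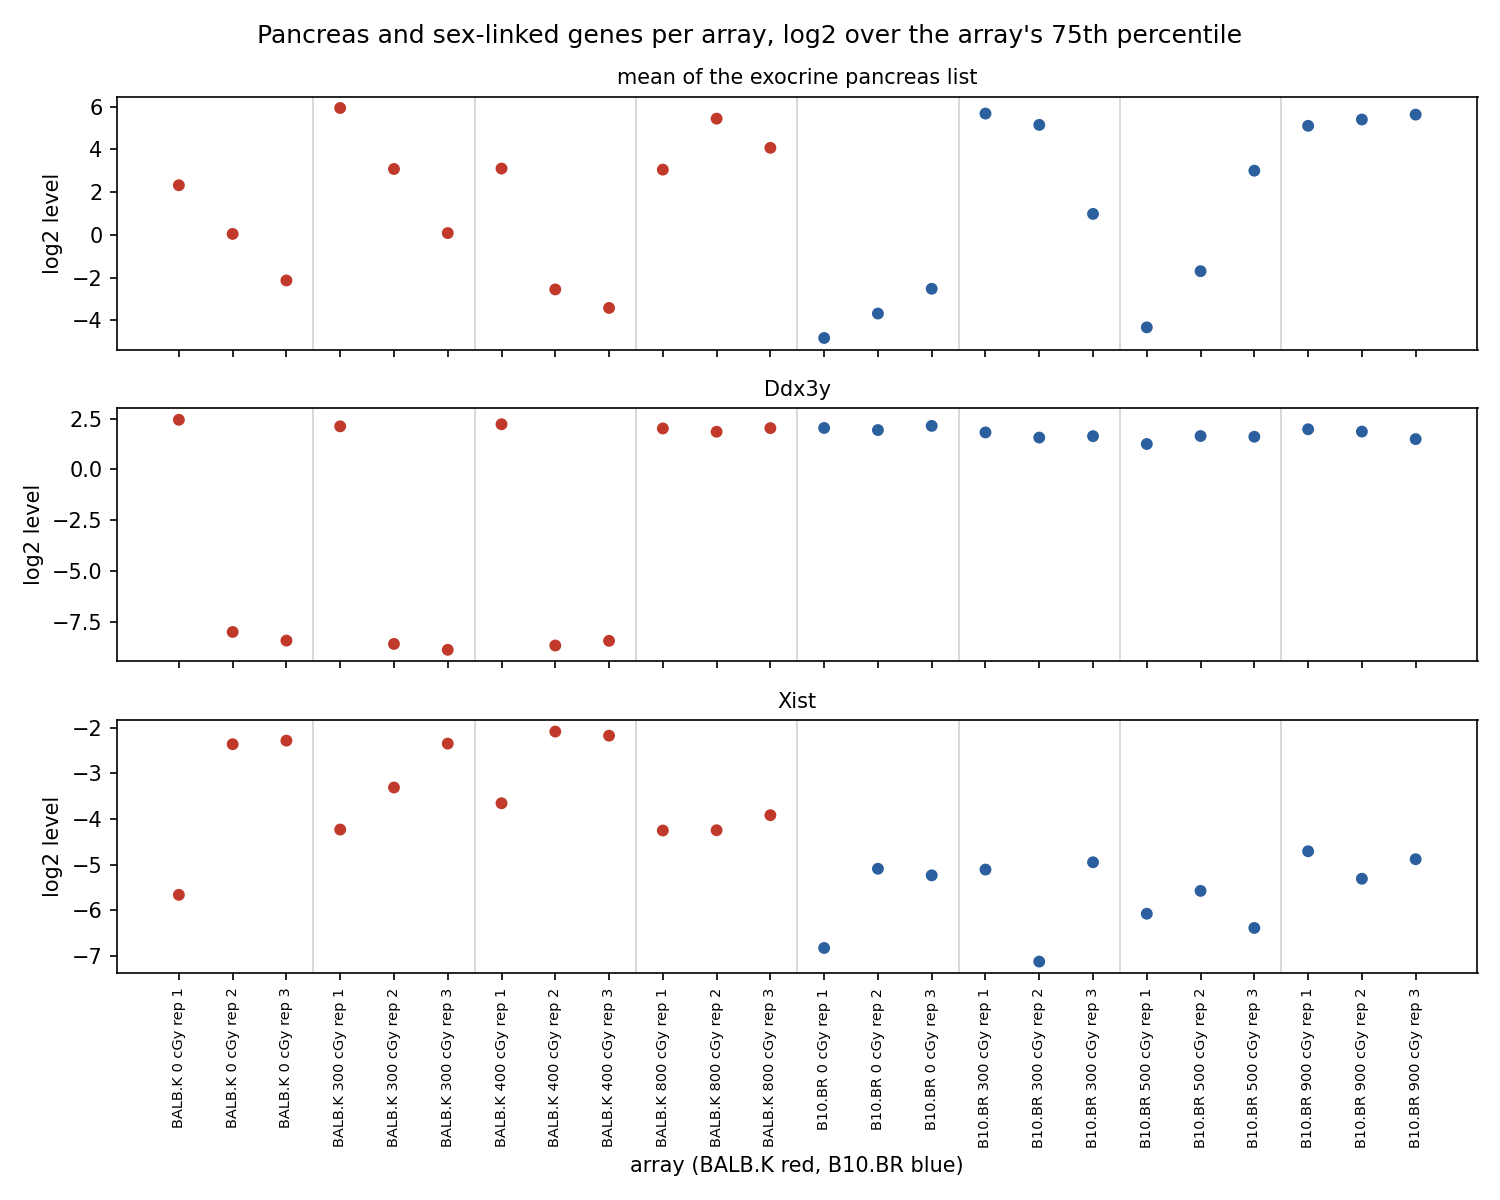
Mean log2 level of the exocrine pancreas list, of Ddx3y and of Xist on each of 24 arrays (points, 3 per group, relative to the array's 75th percentile). The exocrine mean ran from -4.82 to 5.94, and Ddx3y was at -8.0 or lower on 6 BALB.K arrays.

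BALB.K at 300 cGy against 0 shows the response of that strain to the dose both strains received. Genes of red cell formation had among the largest falls, with Klf1 (-6.03 ± 0.29), Rhd (-6.36 ± 0.31) and Btnl10 (-6.95 ± 0.35). Klf1 is the master transcription factor of erythroid cells, and Rhd encodes a red cell surface protein. Among the largest rises were Matn1 (4.99 ± 0.17), Gpnmb (4.0 ± 0.34), Cdkn1a (3.92 ± 0.099), Ifit3 (3.78 ± 0.19) and Mmp13 (3.64 ± 0.20). Cdkn1a encodes the p53-induced inhibitor of cyclin-dependent kinases, and the p53 targets Ccng1 (1.67 ± 0.13) and Bax (1.22 ± 0.084) also rose, while Trp53 itself fell (-0.64 ± 0.11). The cell cycle genes Ccna2 (-3.96 ± 0.19), Cdc6 (-3.83 ± 0.22) and Mki67 (-3.55 ± 0.16) and the repair genes Brca1 (-3.0 ± 0.22) and Blm (-2.98 ± 0.17) fell, and the cell cycle inhibitor Cdkn2a rose (1.66 ± 0.13). In all, 13812 of 29521 features passed, 6124 higher and 7688 lower, 4549 of them at least 2-fold. Of 32 erythroid genes 0 rose, 27 fell and 5 did not pass (median -3.65, -3.86 with the block, adjusted p = 3.31e-20). Of 36 proliferation genes 0 rose, 36 fell and 0 did not pass (median -2.76, -2.95 with the block, adjusted p = 2.56e-31). Of 31 DNA repair genes 1 rose, 23 fell and 7 did not pass (median -0.72, -0.76 with the block, adjusted p = 2.55e-09). Of 34 p53 target genes 25 rose, 4 fell and 5 did not pass (median 1.18, 1.11 with genes at their bound and 1.18 with the block, adjusted p = 5.83e-11).

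Vpreb3 (-1.37 ± 0.12) and Bach2 (-1.34 ± 0.13) of B cells and Cd8b1 (-1.64 ± 0.13), Cd2 (-1.01 ± 0.10) and Cd3e (-0.37 ± 0.11) of T cells fell, by less than the erythroid genes. The plasma cell genes Sdc1 (1.21 ± 0.12) and Pdia4 (1.14 ± 0.12) rose, as did Fcgr1 (2.34 ± 0.12), Cd5l (1.91 ± 0.18) and Cd68 (1.27 ± 0.20) of macrophages, Cd5l being a product of tissue macrophages. S100a8 of neutrophils (0.43 ± 0.25) and Pf4 of platelets (0.41 ± 0.17) did not pass. Of 27 B cell genes 0 rose, 22 fell and 5 did not pass (0 and 23 over the list alone, median -0.80, -0.89 with the block, adjusted p = 4.86e-07, or 0.0623 with estimated correlation). Of 27 T cell genes 1 rose, 17 fell and 9 did not pass (median -0.38, -0.56 with the block, adjusted p = 9.95e-04, or 0.310 with estimated correlation). Of 15 regulatory T cell genes 12 rose, 0 fell and 3 did not pass (median 0.67, 0.66 with genes at their bound and 0.72 with the block, adjusted p = 8.29e-05). Of 15 plasma cell genes 13 rose, 0 fell and 2 did not pass (median 0.76, 0.84 with the block, adjusted p = 3.21e-08). Of 31 macrophage genes 31 rose, 0 fell and 0 did not pass (median 1.23, 1.20 with the block, adjusted p = 5.68e-19). Of 29 neutrophil and granulocyte precursor genes 12 rose, 0 fell and 17 did not pass (10 and 0 over the list alone, median 0.51, 0.26 with the block, adjusted p = 4.77e-04, or 0.389 with estimated correlation). Of 20 dendritic cell genes 9 rose, 0 fell and 11 did not pass (median 0.18, 0.16 with genes at their bound and 0.17 with the block, adjusted p = 0.00454, or 0.0741 with estimated correlation). Of 23 megakaryocyte and platelet genes 14 rose, 1 fell and 8 did not pass (15 and 1 over the list alone, median 0.60, 0.85 with the block, adjusted p = 7.46e-04, or 0.423 with estimated correlation).

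The interferon-induced genes Oas2 (3.22 ± 0.21) and Ifi44 (3.14 ± 0.15) rose, and so did the chemokine Ccl12 (3.36 ± 0.34), with Ccl7 at least 3.84-fold higher. The growth factors Il15 (1.66 ± 0.15), Lif (1.43 ± 0.17) and Igf1 (1.37 ± 0.11) and the stromal genes Lum (1.95 ± 0.21) and Ccl19 (1.82 ± 0.10) rose. Of 33 interferon response genes 31 rose, 1 fell and 1 did not pass (median 1.68, 1.34 with the block, adjusted p = 1.81e-22). Of 29 inflammatory cytokine and chemokine genes 19 rose, 1 fell and 9 did not pass (median 0.80, 0.76 with genes at their bound and 0.60 with the block, adjusted p = 3.09e-06). Of 14 hematopoietic growth factor genes 10 rose, 1 fell and 3 did not pass (median 0.90, 0.86 with genes at their bound and 1.01 with the block, adjusted p = 1.13e-05). Of 31 stroma and endothelium genes 30 rose, 0 fell and 1 did not pass (31 and 0 over the list alone, median 1.07, 1.05 with the block, adjusted p = 1.51e-16). Of 11 adipocyte genes 8 rose, 0 fell and 3 did not pass (9 and 0 over the list alone, median 1.53, 1.27 with the block, adjusted p = 0.00235, or 0.310 with estimated correlation). Of 19 exocrine pancreas genes 0 rose, 0 fell and 19 did not pass (median 3.08, 5.85 with the block, adjusted p = 0.0229, or 0.652 with estimated correlation). For exocrine pancreas genes the call ended with quantile normalization (adjusted p = 0.0686) and median scaling (adjusted p = 0.141), ranging from 6.83e-05 to 0.652 over all settings. The lists that did not pass were apoptosis regulators (12 of 28 rose and 7 fell, median 0.14, adjusted p = 0.0587), NK and cytotoxic cell (6 of 21 rose and 2 fell, median 0.058 or -0.0098 with spike-in scaling, adjusted p = 0.194) and antigen presentation (12 of 22 rose and 6 fell, 12 and 7 over the list alone, median 0.33, adjusted p = 0.0625). Neither did oxidative stress response (10 of 24 rose and 5 fell, median -0.043 or 0.14 with quantile normalization and 0.13 with median scaling, mean 0.081, test pointing up, adjusted p = 0.489) or immediate early and heat shock (4 of 23 rose and 5 fell, median 0.13, adjusted p = 0.961), nor mast cell and basophil (2 of 12 rose and 5 fell, median 0.015 or -0.053 with spike-in scaling, mean -0.080, test pointing up, adjusted p = 0.961) and sex-linked (0 of 5 rose and 0 fell, median -0.062 or 0.11 with quantile normalization and 0.12 with median scaling, adjusted p = 0.913).

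The block equals here the comparison within slide 2 of 1 irradiated with 3 unirradiated arrays, and 11458 features passed with it. Calls ended for Cd3e with median scaling, only the arrays compared, slide as a block, only BALB.K arrays without Y-linked signal or 1 array left out and Cd3e and Trp53 with spike-in scaling. Of the features that passed 44.3% were higher, against 61.9% with median scaling. The median of all genes, -0.12, moved by 0.18 with median scaling, and relative to it lay erythroid at -3.53 and proliferation at -2.64. The count was 7955 with spike-in scaling and 8177 with only the arrays compared.

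At 400 cGy against 0 in BALB.K, Btnl10 (-7.43 ± 0.35), Ahsp (-7.42 ± 0.37), Rhd (-7.17 ± 0.31) and Klf1 (-7.12 ± 0.29) had among the largest falls, Ahsp encoding the chaperone of free alpha-globin. Matn1 (5.55 ± 0.17), Gpnmb (4.97 ± 0.34), Saa3 (4.75 ± 0.71), Cdkn1a (4.15 ± 0.099) and Gdf15 (3.43 ± 0.21) had among the largest rises, Gdf15 being a secreted stress cytokine induced by p53, and Zfp750 was at least 2.67-fold higher. Cdc6 (-4.38 ± 0.22), Ccna2 (-4.34 ± 0.19) and Mki67 (-3.76 ± 0.16) of the cell cycle, Vpreb3 (-2.21 ± 0.12) and Pax5 (-2.08 ± 0.17) of B cells and Cd8b1 (-2.37 ± 0.13) and Cd2 (-1.66 ± 0.10) of T cells fell. Vsig4 (2.38 ± 0.27), Cd163 (2.31 ± 0.37) and Cd68 (1.59 ± 0.20) of macrophages, Mx1 (3.26 ± 0.23) and Ifit3 (3.64 ± 0.19) of the interferon response and Dcn (1.73 ± 0.13) and Cxcl12 (1.42 ± 0.11) of stroma rose, Cxcl12 being the chemokine that retains blood stem cells. In all, 15211 of 29521 features passed, 7548 higher and 7663 lower, 5676 of them at least 2-fold. The erythroid list (32 genes, median -4.22, -4.43 with the block, adjusted p = 4.38e-19) had 1 risen, 27 fallen and 4 not passing. The proliferation list (36 genes, median -3.08, -3.27 with the block, adjusted p = 3.96e-31) had 0 risen, 36 fallen and 0 not passing. The B cell list (27 genes, median -1.40, -1.44 with the block, adjusted p = 1.45e-13) had 0 risen, 24 fallen and 3 not passing. The T cell list (27 genes, median -0.84, -1.06 with the block, adjusted p = 3.11e-08, or 0.0914 with estimated correlation) had 1 risen, 24 fallen and 2 not passing. The interferon response list (33 genes, median 1.51, 0.93 with the block, adjusted p = 1.08e-15, or 0.0914 with estimated correlation) had 31 risen, 2 fallen and 0 not passing. With the block, which rests on the 300 cGy group split over slides 2 and 3, 11475 features passed. Gene calls ended for Saa3 with slide as a block. The share of passing features that were higher was 49.6%, and 67.6% with spike-in scaling. All genes together had a median of 0.0070, which moved by 0.12 with spike-in scaling, and relative to it lay erythroid at -4.23 and proliferation at -3.08. The number that passed was 9770 with spike-in scaling.

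At the myeloablative 800 cGy against 0 in BALB.K, Btnl10 (-8.11 ± 0.35), Klf1 (-7.85 ± 0.29) and Ahsp (-8.57 ± 0.37) of red cells, the B cell transcription factors Ebf1 (-3.76 ± 0.10) and Pax5 (-3.73 ± 0.17), Cd8b1 (-3.57 ± 0.13) and Lef1 (-2.78 ± 0.15) of T cells and Eomes (-2.14 ± 0.13) of natural killer cells fell. Matn1 (6.12 ± 0.17), Cdkn1a (5.35 ± 0.099), Gdf15 (3.97 ± 0.21) and Ddit4l (3.31 ± 0.16) rose, as did Cd163 (3.23 ± 0.37), C1qb (2.78 ± 0.18) and Cd68 (2.66 ± 0.20) of macrophages, Oas2 (3.84 ± 0.21) and Irf7 (3.44 ± 0.24) of the interferon response and Ccl12 (3.93 ± 0.34) and Ccl8 (3.07 ± 0.26), with Ccl7 at least 10.1-fold higher. Reg3b was at least 95.3-fold higher and Reg3a at least 13.4-fold higher, genes of the regenerating family made in gut and pancreas. All 3 of the 800 cGy arrays had Y-linked signal, against 1 of 3 at 0. In all, 17240 of 29521 features passed, 8636 higher and 8604 lower, 7427 of them at least 2-fold. Among 32 erythroid genes (median -4.58, -4.72 with the block, adjusted p = 5.72e-16), 1 rose, 27 fell and 4 did not pass. Among 36 proliferation genes (median -3.18, -3.33 with the block, adjusted p = 6.57e-26), 0 rose, 36 fell and 0 did not pass. The p53 target list (34 genes, median 1.22, 1.15 with genes at their bound and 1.35 with the block, adjusted p = 1.30e-07) had 26 risen, 4 fallen and 4 not passing. Among 27 B cell genes (median -2.59, -2.50 with the block, adjusted p = 4.53e-17), 0 rose, 26 fell and 1 did not pass. Among 27 T cell genes (median -1.57, -1.86 with the block, adjusted p = 3.51e-13), 0 rose, 25 fell and 2 did not pass. The macrophage list (31 genes, median 1.84, 1.62 with the block, adjusted p = 9.44e-16) had 29 risen, 0 fallen and 2 not passing. Among 33 interferon response genes (median 1.67, 1.23 with the block, adjusted p = 1.39e-14, or 0.119 with estimated correlation), 31 rose, 2 fell and 0 did not pass. The exocrine pancreas list (19 genes, 0 and 0 over the list alone, median 4.08, 8.49 with the block, adjusted p = 0.0447, or 0.693 with estimated correlation) had 4 risen, 0 fallen and 15 not passing. Exocrine pancreas genes lost their call with spike-in scaling (adjusted p = 0.133), ranging from 1.97e-04 to 0.693 over all settings. The block left 13442 features. Higher features made up 50.1% of those that passed, but 78.0% with spike-in scaling. For all genes the median was 0.077 and moved by 0.37 with spike-in scaling and -0.19 with normexp background correction, and relative to it lay erythroid at -4.66 and proliferation at -3.26.

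In B10.BR at 300 cGy against 0 large falls were again of erythroid genes, with Rhd (-8.33 ± 0.31), Btnl10 (-7.23 ± 0.35), Klf1 (-6.50 ± 0.29) and Ahsp (-7.19 ± 0.37). The p53 targets Cdkn1a (3.82 ± 0.099), Gdf15 (3.47 ± 0.21), Psrc1 (2.77 ± 0.15) and Ccng1 (1.87 ± 0.13) rose, Trp53 fell (-0.31 ± 0.11, or 0.037 with spike-in scaling) and Mdm2 did not pass (0.31 ± 0.75). The largest rises were of digestive enzymes, with Cela2a (10.30 ± 2.52) and Prss1 (8.99 ± 2.13). Ccna2 (-2.19 ± 0.19) and Mki67 (-2.15 ± 0.16) of the cell cycle, Bach2 (-1.59 ± 0.13) and Ebf1 (-1.46 ± 0.10) of B cells and Lef1 (-1.98 ± 0.15), Cd8b1 (-1.67 ± 0.13) and Cd3e (-0.84 ± 0.11) of T cells fell. Gpnmb (5.13 ± 0.34), Fcgr1 (2.05 ± 0.12) and Cd68 (2.15 ± 0.20) of macrophages, Stfa1 (2.83 ± 0.28), Mmp9 (2.15 ± 0.15) and S100a8 (1.03 ± 0.25) of neutrophils and Ifi44 (3.31 ± 0.15) and Ifit3 (3.07 ± 0.19) of the interferon response rose. Ccl12 (2.83 ± 0.34) and Il12b (1.99 ± 0.16) of inflammation, the growth factors Igf1 (1.74 ± 0.11) and Il7 (1.36 ± 0.11) and Hmox1 (1.79 ± 0.19), which breaks down heme, rose. The immediate early genes Egr1 (-1.48 ± 0.39) and Nr4a1 (-1.23 ± 0.21) fell. In all, 12328 of 29521 features passed, 5528 higher and 6800 lower, 2917 of them at least 2-fold.

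Of 32 erythroid genes 1 rose, 29 fell and 2 did not pass (median -3.52, adjusted p = 4.19e-23). Of 36 proliferation genes 0 rose, 35 fell and 1 did not pass (median -1.17, adjusted p = 1.40e-18, or 0.0645 with estimated correlation). Among 34 p53 target genes (23 and 4 over the list alone, median 0.66, 0.65 with genes at their bound, adjusted p = 2.05e-08), 22 rose, 4 fell and 8 did not pass. Of 27 B cell genes 0 rose, 26 fell and 1 did not pass (median -0.89, adjusted p = 7.65e-13). Of 27 T cell genes 0 rose, 23 fell and 4 did not pass (0 and 25 over the list alone, median -0.92, adjusted p = 9.51e-11, or 0.0533 with estimated correlation). Among 31 macrophage genes (median 1.26, adjusted p = 3.15e-21), 31 rose, 0 fell and 0 did not pass. The neutrophil and granulocyte precursor list (29 genes, 24 and 0 over the list alone, median 1.07, adjusted p = 6.72e-08, or 0.195 with estimated correlation) had 21 risen, 0 fallen and 8 not passing. Of 33 interferon response genes 31 rose, 0 fell and 2 did not pass (median 1.83, adjusted p = 4.35e-26). Among 19 exocrine pancreas genes (median 8.0, 7.42 with genes at their bound, adjusted p = 6.98e-07, or 0.276 with estimated correlation), 19 rose, 0 fell and 0 did not pass. All 6 arrays lay on slide 1. The calls ending were those of Cd3e with spike-in scaling, Egr1 and Trp53 with only the arrays compared, Trp53 with an intensity trend or 1 array left out and Egr1, Prss1 and Trp53 with the exocrine level as a covariate. Of the features that passed 44.8% were higher, against 86.5% with spike-in scaling. The median of all genes, -0.070, moved by 0.35 with spike-in scaling, and relative to it lay erythroid at -3.45 and proliferation at -1.10. The number was 7268 with spike-in scaling.

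At 500 cGy against 0 in B10.BR, Rhd was at least 384-fold lower and Btnl10 at least 339.6-fold lower, and Ahsp (-9.61 ± 0.37) and Klf1 (-7.95 ± 0.29) fell. Gpnmb (5.38 ± 0.34), Slfn4 (4.95 ± 0.21), Saa3 (4.68 ± 0.71), Cdkn1a (4.45 ± 0.099) and Phlda3 (3.09 ± 0.095) rose, Slfn4 being an interferon-responsive gene of myeloid cells. Ccna2 (-2.46 ± 0.19) and Mki67 (-2.37 ± 0.16) of the cell cycle, Ebf1 (-2.55 ± 0.10) and Fcer2a (-2.49 ± 0.18) of B cells, Lef1 (-2.97 ± 0.15) and Cd8b1 (-2.86 ± 0.13) of T cells and Myc (-1.22 ± 0.14) fell. Siglec1 (2.58 ± 0.20) and Fcgr1 (2.54 ± 0.12) of macrophages, Ifi44 (4.0 ± 0.15) and Irf7 (3.50 ± 0.24), Ccl12 (3.89 ± 0.34) and Il7 (2.02 ± 0.11) rose. In all, 14413 of 29521 features passed, 6517 higher and 7896 lower, 4944 of them at least 2-fold. The erythroid list (32 genes, median -4.07, -4.08 with the block, adjusted p = 9.01e-20) had 1 risen, 29 fallen and 2 not passing. The proliferation list (36 genes, median -1.37, -1.49 with the block, adjusted p = 2.15e-17, or 0.0705 with estimated correlation) had 0 risen, 35 fallen and 1 not passing. The B cell list (27 genes, 0 and 27 over the list alone, median -1.68, -1.83 with the block, adjusted p = 7.43e-18) had 0 risen, 26 fallen and 1 not passing. The T cell list (27 genes, median -1.48, -1.59 with the block, adjusted p = 1.96e-13) had 1 risen, 25 fallen and 1 not passing. The interferon response list (33 genes, median 2.03, 2.04 with the block, adjusted p = 3.10e-22) had 31 risen, 1 fallen and 1 not passing. With the block, equal here to the comparison within slide 1, 13908 features passed. The share of passing features that were higher was 45.2%, and 79.5% with spike-in scaling. All genes together had a median of -0.070, which moved by 0.33 with spike-in scaling, and relative to it lay erythroid at -4.0 and proliferation at -1.30. Passing features numbered 8917 with spike-in scaling.

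After the myeloablative 900 cGy against 0 in B10.BR, Rhd was at least 405-fold lower, Kel at least 591-fold lower and Epb42 at least 153-fold lower, all membrane proteins of red cells, and Ahsp (-11.94 ± 0.37) and Slc4a1 (-8.58 ± 0.30) fell. Cd8b1 (-4.57 ± 0.13), Lef1 (-3.95 ± 0.15) and Cd3e (-2.13 ± 0.11) of T cells, Ebf1 (-3.38 ± 0.10) and Fcer2a (-3.30 ± 0.18) of B cells, Ccna2 (-3.29 ± 0.19) and Mki67 (-2.98 ± 0.16) of the cell cycle and Myc (-2.10 ± 0.14) fell. Cdkn1a (4.95 ± 0.099), Gdf15 (4.46 ± 0.21) and Phlda3 (3.31 ± 0.095) rose, with Gpnmb (4.89 ± 0.34) and Siglec1 (3.04 ± 0.20) of macrophages, Ifi44 (3.41 ± 0.15), Ccl12 (3.74 ± 0.34) and Il7 (2.42 ± 0.11) and Igf1 (2.28 ± 0.11). Digestive enzymes were among the largest rises, with Cela2a (11.91 ± 2.52) and Pnliprp1 (10.71 ± 2.23), and Reg2 was at least 831-fold higher. In all, 16001 of 29521 features passed, 7624 higher and 8377 lower, 6566 of them at least 2-fold. Among 32 erythroid genes (1 and 30 over the list alone, median -4.43, -4.52 with the block, adjusted p = 1.72e-19), 1 rose, 29 fell and 2 did not pass. Among 36 proliferation genes (median -1.99, -2.34 with the block, adjusted p = 5.24e-20, or 0.0625 with estimated correlation), 0 rose, 36 fell and 0 did not pass. Of 34 p53 target genes 25 rose, 4 fell and 5 did not pass (median 1.03, 0.93 with genes at their bound and 1.0 with the block, adjusted p = 1.95e-07). Among 27 B cell genes (median -2.39, -2.78 with the block, adjusted p = 5.24e-20), 0 rose, 27 fell and 0 did not pass. Among 27 T cell genes (1 and 25 over the list alone, median -2.15, -2.50 with the block, adjusted p = 5.25e-16), 0 rose, 25 fell and 2 did not pass. Among 33 interferon response genes (31 and 1 over the list alone, median 1.34, 1.48 with the block, adjusted p = 8.58e-14, or 0.135 with estimated correlation), 31 rose, 0 fell and 2 did not pass. Of 19 exocrine pancreas genes 19 rose, 0 fell and 0 did not pass (median 9.56, 8.86 with genes at their bound and 3.01 with the block, adjusted p = 2.36e-05, or 0.379 with estimated correlation). The exocrine pancreas call ended with slide as a block (adjusted p = 0.137), ranging from 1.44e-06 to 0.379 over all settings. The block, which rests on the 500 cGy group split over slides 1 and 2, left 10970 features. The calls the block ended were those of Cela2a, Pnliprp1 and Reg2. Higher features made up 47.6% of those that passed, but 80.3% with spike-in scaling. For all genes the median was 0.0038 and moved by 0.41 with spike-in scaling, and relative to it lay erythroid at -4.43 and proliferation at -1.99.

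**Figure D2:**
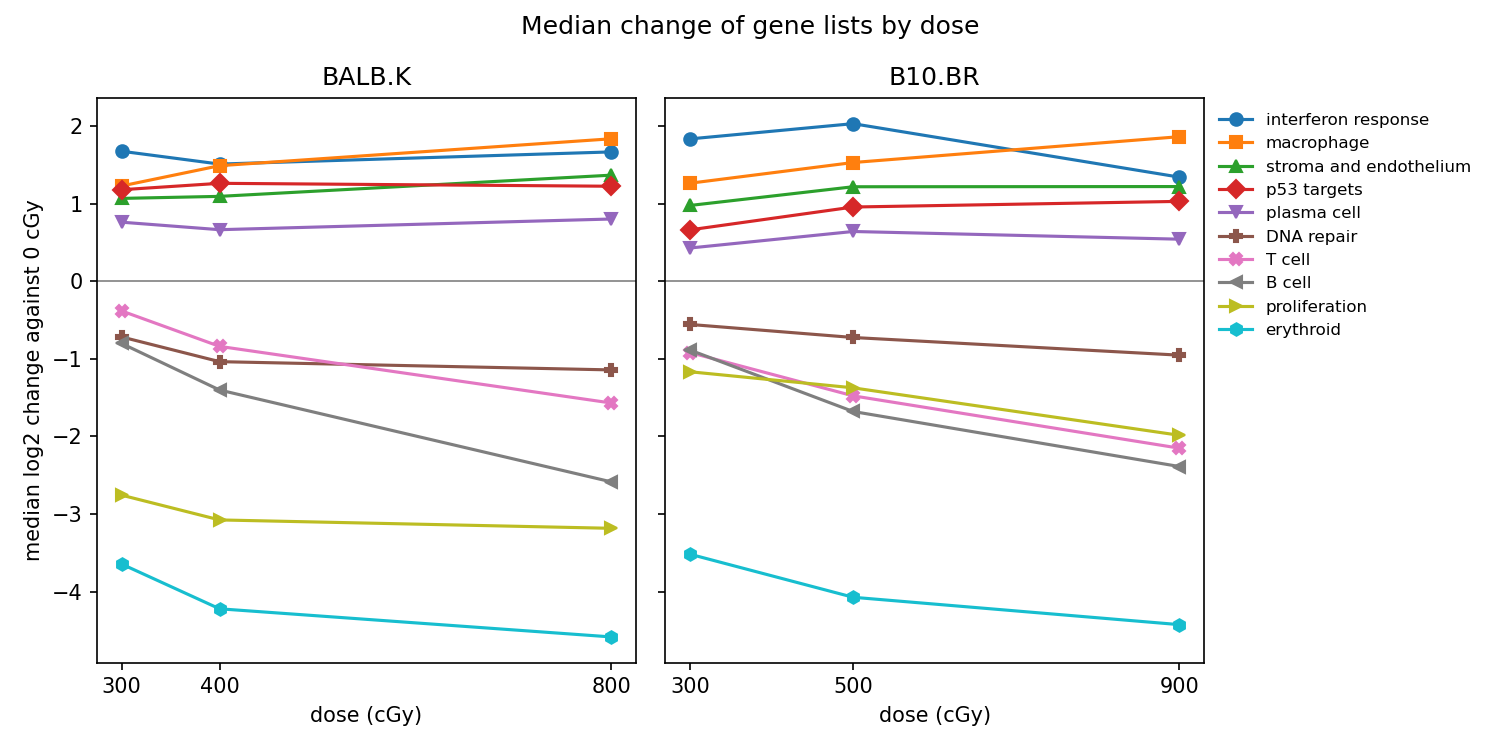
Median log2 change against 0 cGy (vertical axis) of 10 gene lists by dose in cGy (horizontal axis), BALB.K left and B10.BR right. The proliferation list was at -2.76, -3.08 and -3.18 in BALB.K and -1.17, -1.37 and -1.99 in B10.BR, and none of the 10 lists changed sign with the other array scalings.

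**Figure D3:**
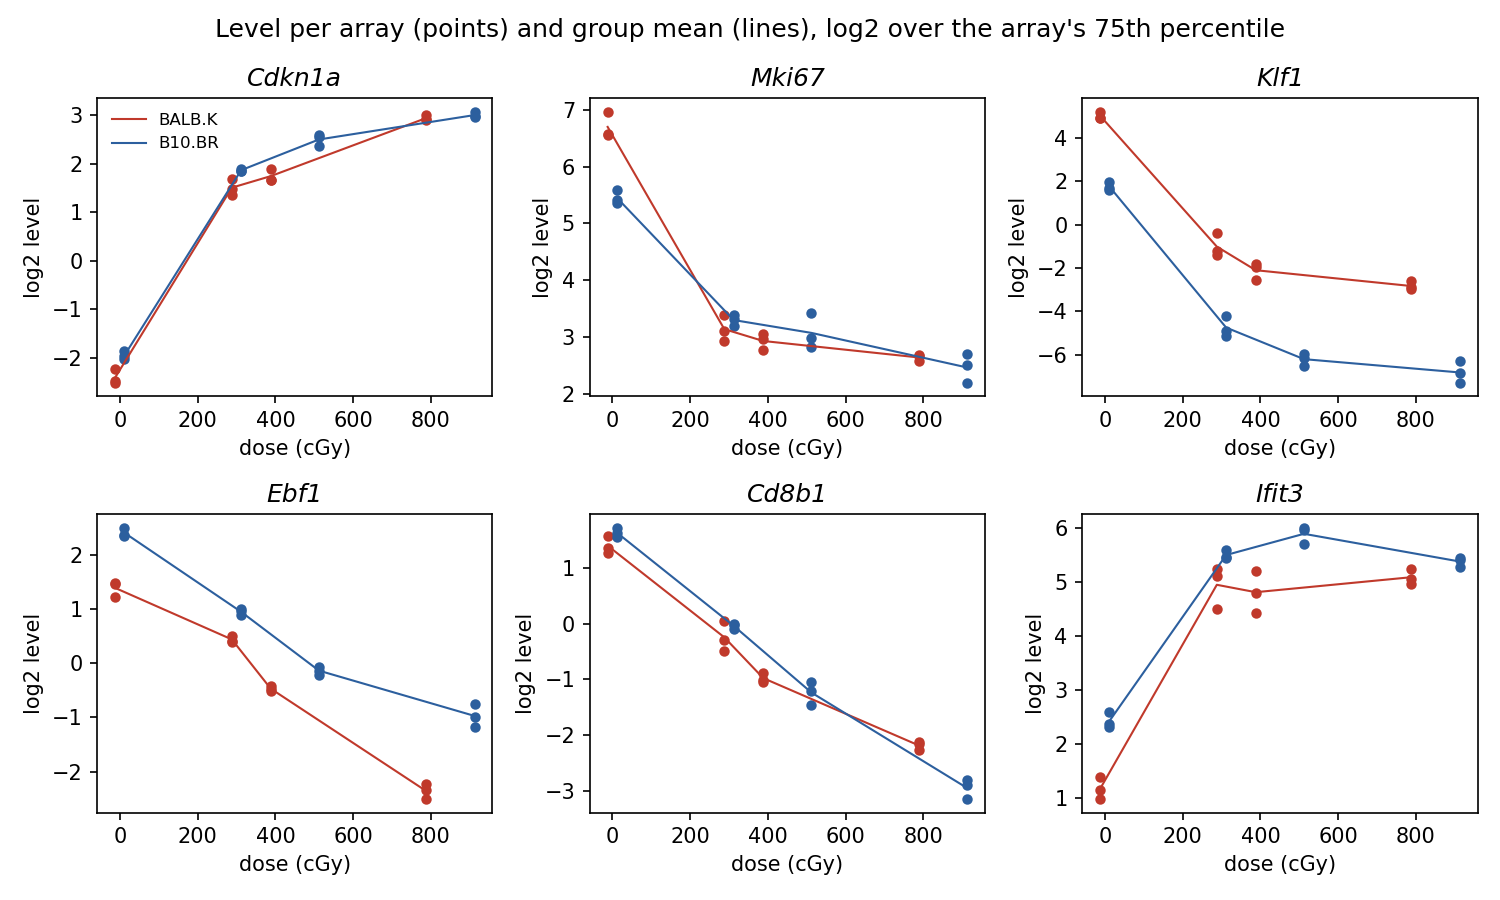
Log2 level of 6 genes relative to the array's 75th percentile (vertical axis) by dose in cGy (horizontal axis), 3 arrays per group as points and group means as lines, BALB.K red and B10.BR blue. Cdkn1a was higher on each irradiated array than on the unirradiated arrays of its strain, and Klf1 lower.

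The 300 cGy responses of the 2 strains share no arrays. Klf1, Rhd and Mki67 fell and Cdkn1a, Ifit3 and Gpnmb rose in both. Of the features tested, 4190 were higher in both strains, against 1147 if the calls were independent, and 4312 were lower in both, against 1771. Opposite calls numbered 160, against 2850.3. The sum of the shared calls, 8502, was 3835 with spike-in scaling. Across genes, which are not independent replicates, Pearson's r of the changes was 0.681 and Spearman's rho 0.615.

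Between 300 and 400 cGy in BALB.K, lymphocyte genes fell further. Cr2 (-1.04 ± 0.10), Tnfrsf13c (-0.92 ± 0.11) and Ebf1 (-0.91 ± 0.10) of B cells and Cd8b1 (-0.73 ± 0.13) and Lef1 (-0.73 ± 0.15) of T cells fell, as did Car1 (-1.19 ± 0.24) and Klf1 (-1.09 ± 0.29) of red cells, Mcm2 (-0.70 ± 0.11) and Mcm5 (-0.55 ± 0.11) of DNA replication and Cd40 (-0.81 ± 0.11). Mertk (0.59 ± 0.12) of macrophages rose, while Cdkn1a (0.24 ± 0.099) and Mki67 (-0.21 ± 0.16) did not pass. In all, 1410 of 29521 features passed, 936 higher and 474 lower, 296 of them at least 2-fold. Of 27 B cell genes 0 rose, 20 fell and 7 did not pass (0 and 22 over the list alone, median -0.63, -0.67 with the block, adjusted p = 2.32e-30). Of 27 T cell genes 0 rose, 12 fell and 15 did not pass (0 and 19 over the list alone, median -0.44, -0.43 with the block, adjusted p = 9.77e-18). Of 36 proliferation genes 0 rose, 4 fell and 32 did not pass (0 and 12 over the list alone, median -0.32, -0.44 with the block, adjusted p = 5.37e-13, or 0.221 with estimated correlation). Of 32 erythroid genes 1 rose, 4 fell and 27 did not pass (1 and 5 over the list alone, median -0.14, -0.21 with the block and 0.053 with spike-in scaling, adjusted p = 8.45e-04, or 0.564 with estimated correlation). The exocrine pancreas list (19 genes, median -4.39, -2.88 with the block, adjusted p = 2.79e-08, or 0.476 with estimated correlation) had 0 risen, 0 fallen and 19 not passing. The block equals the comparison within slide 3. Gene calls ending were those of Mertk with median scaling, 10 genes with spike-in scaling, Klf1 with no filter, 11 genes with only the arrays compared, Klf1, Lef1 and Mertk with the exocrine level as a covariate, Klf1 and Mcm5 with only BALB.K arrays without Y-linked signal and 5 genes with 1 array left out. Of the features that passed 66.4% were higher, against 46.9% with quantile normalization, 11.6% with median scaling and 99.4% with spike-in scaling. The median of all genes, 0.063, moved by -0.22 with median scaling and 0.19 with spike-in scaling, and relative to it lay B cell at -0.70, T cell at -0.50 and erythroid at -0.20. The number was 5167 with median scaling, 784 with spike-in scaling, 2 with only the arrays compared, 3808 with array weights, 2176 with slide as a block and 616 with the exocrine level as a covariate. Leaving out 1 array gave 254 to 2184 (without 300 cGy replicates 3 and 1 in turn).

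From 400 to 800 cGy in BALB.K, Cxcr5 (-2.06 ± 0.16), Ebf1 (-1.89 ± 0.10) and Cr2 (-1.83 ± 0.10) of B cells, Il7r (-1.84 ± 0.26), Skap1 (-1.39 ± 0.12) and Cd3e (-0.64 ± 0.11) of T cells and Eomes (-0.95 ± 0.13) and Klrd1 (-0.84 ± 0.092) of natural killer cells fell. Cdkn1a rose (1.20 ± 0.099), with Cd14 (1.15 ± 0.12), Cd68 (1.07 ± 0.20) and C1qb (0.90 ± 0.18) of macrophages, Col3a1 (1.12 ± 0.13) and Acta2 (0.94 ± 0.17) of stroma, Tubb1 (1.02 ± 0.22) of platelets and Irf7 (1.65 ± 0.24). Mki67 (-0.29 ± 0.16) did not pass, and the exocrine gene Reg1 rose (6.10 ± 2.05). In all, 5500 of 29521 features passed, 2558 higher and 2942 lower, 661 of them at least 2-fold. The B cell list (27 genes, 0 and 24 over the list alone, median -1.03, adjusted p = 9.62e-28) had 0 risen, 23 fallen and 4 not passing. The T cell list (27 genes, 0 and 25 over the list alone, median -0.86, adjusted p = 1.45e-22) had 0 risen, 23 fallen and 4 not passing. Of 21 NK and cytotoxic cell genes 0 rose, 10 fell and 11 did not pass (0 and 12 over the list alone, median -0.34, adjusted p = 1.22e-04, or 0.316 with estimated correlation). Of 31 macrophage genes 10 rose, 0 fell and 21 did not pass (11 and 0 over the list alone, median 0.13, adjusted p = 5.18e-04, or 0.492 with estimated correlation). Among 19 exocrine pancreas genes (18 and 0 over the list alone, median 5.50, adjusted p = 7.50e-06, or 0.593 with estimated correlation), 1 rose, 0 fell and 18 did not pass. All arrays lay on slide 3. Settings ended the calls of Cd3e, Eomes, Klrd1 and Reg1 with spike-in scaling, Reg1 with no filter, only the arrays compared, an intensity trend, Y-linked signal as a covariate or 1 array left out and Acta2, Cd68, Reg1 and Tubb1 with only BALB.K arrays with Y-linked signal. The share of passing features that were higher was 46.5%, and 35.8% with median scaling and 85.5% with spike-in scaling. All genes together had a median of 0.018, which moved by 0.25 with spike-in scaling, and relative to it lay B cell at -1.04, T cell at -0.88 and macrophage at 0.11. Passing features were 1650 with spike-in scaling, 13487 with array weights and 1917 with only BALB.K arrays with Y-linked signal. Leaving out 1 array gave 3175 (without 800 cGy replicate 2) to 4793 (without 400 cGy replicate 1).

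Between 300 and 500 cGy in B10.BR, Fcer2a (-1.31 ± 0.18), Pax5 (-1.23 ± 0.17) and Ebf1 (-1.09 ± 0.10) of B cells, Cd8b1 (-1.19 ± 0.13), Lef1 (-0.99 ± 0.15) and Cd3e (-0.52 ± 0.11) of T cells and Ahsp (-2.42 ± 0.37) and Trim10 (-1.52 ± 0.30) of red cells fell. The p53 targets Cdkn1a (0.63 ± 0.099) and Phlda3 (0.48 ± 0.095) and Il7 (0.66 ± 0.11) rose, and Mki67 (-0.23 ± 0.16) did not pass. In all, 474 of 29521 features passed, 200 higher and 274 lower, 55 of them at least 2-fold. Among 27 B cell genes (0 and 26 over the list alone, median -0.80, -0.92 with the block, adjusted p = 8.40e-44), 0 rose, 21 fell and 6 did not pass. Among 27 T cell genes (0 and 21 over the list alone, median -0.52, -0.57 with the block, adjusted p = 4.58e-24), 0 rose, 12 fell and 15 did not pass. The erythroid list (32 genes, 0 and 17 over the list alone, median -0.53, -0.49 with genes at their bound and -0.48 with the block, adjusted p = 3.39e-10, or 0.173 with estimated correlation) had 0 risen, 7 fallen and 25 not passing. The p53 target list (34 genes, 5 and 0 over the list alone, median 0.16, 0.15 with genes at their bound and 0.13 with the block, adjusted p = 1.15e-05, or 0.0594 with estimated correlation) had 3 risen, 0 fallen and 31 not passing. Of 19 exocrine pancreas genes 0 rose, 0 fell and 19 did not pass (0 and 19 over the list alone, median -5.0, -7.20 with the block, adjusted p = 1.52e-11, or 0.224 with estimated correlation). The block equals the comparison within slide 1. The calls lost were those of Cd3e with median scaling, 10 genes with spike-in scaling, Cdkn1a with the mean of all probes, 11 genes with only the arrays compared and Cd3e, Phlda3 and Trim10 with the exocrine level as a covariate or 1 array left out. Higher features made up 42.2% of those that passed, but 59.1% with median scaling, 0% with spike-in scaling, 52.4% with normexp background correction and 55.2% with the deposited matrix. The count moved to 3 with spike-in scaling, 0 with only the arrays compared, 3671 with array weights, 952 with slide as a block, 221 with the exocrine level as a covariate and 804 with Y-linked signal as a covariate (the 0 is limma's, with 3614 features at an unadjusted p under 0.05). Leaving out 1 array gave 132 to 799 (without 500 cGy replicates 1 and 3 in turn).

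From 500 to 900 cGy in B10.BR, Cd8b1 (-1.71 ± 0.13), Cd8a (-1.33 ± 0.084), Lef1 (-0.98 ± 0.15) and Cd3e (-0.77 ± 0.11) of T cells, Fcmr (-1.10 ± 0.11) and Cr2 (-1.06 ± 0.10) of B cells and Cd209a (-1.33 ± 0.13), Ccr7 (-1.03 ± 0.099) and Flt3 (-0.95 ± 0.10) of dendritic cells fell. The interferon genes Oasl1 (-1.23 ± 0.17) and Zbp1 (-0.90 ± 0.16), the cell cycle genes Nusap1 (-0.86 ± 0.18) and Mki67 (-0.61 ± 0.16), Slc4a1 (-2.49 ± 0.30) of red cells and Foxp3 (-0.50 ± 0.097) of regulatory T cells fell. Cdkn1a (0.50 ± 0.099) and Cd14 (0.87 ± 0.12) rose, as did the pancreas gene Reg1 (7.57 ± 2.05). In all, 1355 of 29521 features passed, 396 higher and 959 lower, 166 of them at least 2-fold. Of 27 T cell genes 0 rose, 18 fell and 9 did not pass (0 and 24 over the list alone, median -0.67, -0.90 with the block, adjusted p = 1.43e-29). Of 27 B cell genes 0 rose, 21 fell and 6 did not pass (0 and 26 over the list alone, median -0.71, -0.90 with the block, adjusted p = 1.78e-33). Of 33 interferon response genes 0 rose, 16 fell and 17 did not pass (0 and 29 over the list alone, median -0.51, -0.46 with the block, adjusted p = 4.33e-21, or 0.0590 with estimated correlation). The dendritic cell list (20 genes, 0 and 7 over the list alone, median -0.19, -0.29 with the block, adjusted p = 8.50e-07) had 0 risen, 6 fallen and 14 not passing. The exocrine pancreas list (19 genes, 19 and 0 over the list alone, median 6.39, 2.58 with the block, adjusted p = 4.68e-13, or 0.155 with estimated correlation) had 4 risen, 0 fallen and 15 not passing. The block equals the comparison within slide 2. Calls were lost for Cdkn1a with median scaling or the mean of all probes, 14 genes with spike-in scaling, Reg1 with no filter, an intensity trend or slide as a random block, 7 genes with only the arrays compared, Cdkn1a and Reg1 with slide as a block, Cdkn1a, Mki67, Nusap1 and Zbp1 with the exocrine level as a covariate and Mki67, Nusap1 and Reg1 with 1 array left out. Of the features that passed 29.2% were higher, against 10.9% with median scaling and 44.1% with spike-in scaling. The number moved to 34 with spike-in scaling, 147 with only the arrays compared, 3105 with array weights, 723 with slide as a block and 487 with the exocrine level as a covariate. Leaving out 1 array gave 540 to 1263 (without 900 cGy replicates 3 and 2 in turn).

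Unirradiated B10.BR was set against unirradiated BALB.K. Vps16 (9.41 ± 0.13) and Pnp2 (6.67 ± 0.28) were higher in B10.BR, Trim12a was at least 2359-fold higher and H2-T3 at least 56.2-fold higher. Jhy (-8.41 ± 0.28) was lower, Ifi202b was at least 563-fold lower and Serpina3a at least 59.2-fold lower, Trim12a and Ifi202b belonging to innate immune families. Strain variants under a probe, which change its signal without a change in expression, were not examined here. Erythroid and cell cycle genes were lower in B10.BR, among them Rhd (-3.73 ± 0.31) and Klf1 (-3.27 ± 0.29) and Ttk (-2.01 ± 0.22), Cdc6 (-2.01 ± 0.22) and Mki67 (-1.25 ± 0.16), and so was Cdkn2a (-1.56 ± 0.13). Ly6d (3.15 ± 0.17) and Vpreb3 (1.12 ± 0.12) of B cells, Lef1 (1.28 ± 0.15) of T cells, Klrd1 (2.06 ± 0.092) of natural killer cells and Fos (2.93 ± 0.69) and Egr1 (1.95 ± 0.39) were higher. Ncr1 was lower (-1.72 ± 0.17). Cdkn1a was higher on its probe (0.46 ± 0.099, with 2 of 2 other probes going the other way), lower with the mean of its probes (-0.48, which passed) and at -0.27, not passing, with spike-in scaling. Xist was lower (-2.28 ± 0.77) and Eif2s3y of the Y chromosome higher (6.62 ± 2.41). Y-linked signal was on all 3 B10.BR arrays and on 1 of 3 BALB.K arrays, so that strain and sex mix may differ together. In all, 15760 of 29521 features passed, 6685 higher and 9075 lower, 5889 of them at least 2-fold. Among 32 erythroid genes (median -1.31, -1.60 with the block, adjusted p = 3.51e-06, or 0.410 with estimated correlation), 2 were higher in B10.BR, 27 lower and 3 did not pass. The proliferation list (36 genes, 1 and 35 over the list alone, median -1.06, -0.76 with the block, adjusted p = 1.85e-11, or 0.353 with estimated correlation) had 0 higher in B10.BR, 35 lower and 1 not passing. The B cell list (27 genes, median 0.33, 0.56 with the block and -0.40 with spike-in scaling, adjusted p = 1.79e-05, or 0.353 with estimated correlation) had 14 higher in B10.BR, 1 lower and 12 not passing. The T cell list (27 genes, median 0.19, 0.50 with the block and -0.54 with spike-in scaling, adjusted p = 0.0176, or 0.581 with estimated correlation) had 10 higher in B10.BR, 2 lower and 15 not passing. For T cell genes the call ended with quantile normalization (adjusted p = 0.113) and spike-in scaling (adjusted p = 0.0635), ranging from 1.36e-05 to 0.581 over all settings. Of 23 immediate early and heat shock genes 16 were higher in B10.BR, 1 lower and 6 did not pass (17 and 2 over the list alone, median 0.93, 1.19 with the block, adjusted p = 3.09e-05, or 0.353 with estimated correlation). The block, which rests on the B10.BR 500 cGy group split over slides 1 and 2, left 5743 features. Calls not kept were those of Egr1, Eif2s3y and Xist with only the arrays compared or slide as a block and Eif2s3y and Xist with Y-linked signal as a covariate or 1 array left out. The share of passing features that were higher was 42.4%, and 69.2% with median scaling and 5.11% with spike-in scaling. All genes together had a median of -0.10, which moved by 0.31 with median scaling and -0.73 with spike-in scaling, and relative to it lay erythroid at -1.21, proliferation at -0.96, B cell at 0.43 and T cell at 0.29.

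The strains' responses to 300 cGy were compared by the interaction, the change in B10.BR minus that in BALB.K. Cell cycle genes fell less in B10.BR, with differences for Ttk (2.28 ± 0.31), Nusap1 (2.08 ± 0.25), Prc1 (1.93 ± 0.23) and Mki67 (1.41 ± 0.23) and for Brca1 (2.20 ± 0.32), Blm (1.54 ± 0.24) and Rad54l (1.53 ± 0.18) of DNA repair. Nxpe4 (3.62 ± 0.27) and Mst1r (3.49 ± 0.31) had the largest positive differences among named genes above background in every group, and Pnp2 (-3.02 ± 0.39) a large negative one. The change in B10.BR was lower for Lef1 (-1.27 ± 0.21) and Cd3d (-0.97 ± 0.24) of T cells, Ly6d (-1.17 ± 0.24) and Cr2 (-0.83 ± 0.14) of B cells, Pdia4 (-0.93 ± 0.16) and Mzb1 (-0.79 ± 0.14) of plasma cells, Cd209a (-1.39 ± 0.18) and Clec10a (-1.05 ± 0.18) of dendritic cells and Nr4a1 (-1.44 ± 0.29). It was higher for Gclc (1.04 ± 0.16) and Nqo1 (1.02 ± 0.15), which act against oxidative stress. No difference was called for Cdkn1a on its probe (-0.098 ± 0.14, with 2 of 2 other probes going the other way), while the mean of its probes passed at 1.24. In all, 3217 of 29521 features passed, 1781 higher and 1436 lower, 1150 of them at least 2-fold.

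Among 36 proliferation genes (median 1.5, 1.74 with the block, adjusted p = 1.58e-41, or 0.0507 with estimated correlation), 36 had a higher change in B10.BR, 0 a lower one and 0 did not pass. Their mean level was 3.10 in BALB.K and 2.05 in B10.BR at 0 cGy, and 0.38 and 0.83 at 300 cGy. The DNA repair list (31 genes, 14 and 1 over the list alone, median 0.34, 0.41 with the block, adjusted p = 1.92e-06, or 0.108 with estimated correlation) had 13 with a higher change in B10.BR, 1 with a lower one and 17 not passing. Among 27 T cell genes (1 and 13 over the list alone, median -0.44, -0.34 with the block, adjusted p = 1.36e-06, or 0.227 with estimated correlation), 1 had a higher change in B10.BR, 9 a lower one and 17 did not pass. The plasma cell list (15 genes, median -0.36, -0.41 with the block and 0.063 with spike-in scaling, adjusted p = 1.16e-04, or 0.108 with estimated correlation) had 0 with a higher change in B10.BR, 6 with a lower one and 9 not passing. Among 20 dendritic cell genes (1 and 10 over the list alone, median -0.40, -0.24 with the block and 0.024 with spike-in scaling, adjusted p = 7.75e-05, or 0.0530 with estimated correlation), 0 had a higher change in B10.BR, 6 a lower one and 14 did not pass. Among 19 exocrine pancreas genes (median 4.75, 1.93 with the block, adjusted p = 0.00167, or 0.691 with estimated correlation), 0 had a higher change in B10.BR, 0 a lower one and 19 did not pass. Exocrine pancreas genes lost their call with slide as a block (adjusted p = 0.446), ranging from 5.64e-06 to 0.691 over all settings. The block equals the difference between slide 1 for B10.BR and slide 2 for BALB.K, and 2383 features passed with it. Differences no longer called were those of 9 genes with spike-in scaling, Cd3d, Ly6d and Nr4a1 with only the arrays compared and Cd3d and Ly6d with slide as a block. Higher features made up 55.4% of those that passed, but 21% with median scaling and 97.3% with spike-in scaling. For all genes the median was 0.025 and moved by -0.22 with median scaling and 0.42 with spike-in scaling, and relative to it lay proliferation at 1.48 and T cell at -0.46. The count of differences was 5207 with median scaling, 1578 with spike-in scaling and 873 with only the arrays compared. Leaving out 1 array gave 1893 (without B10.BR 0 cGy replicate 3) to 4753 (without BALB.K 0 cGy replicate 1).

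At the highest doses, 900 cGy in B10.BR and 800 cGy in BALB.K, strain and dose differ together. So may slide and sex mix. No slide held both groups of a strain, and Y-linked signal was on more BALB.K arrays at 800 than at 0 cGy but on all B10.BR arrays. Cdc6 (1.88 ± 0.31), Nusap1 (1.77 ± 0.25) and Mki67 (1.07 ± 0.23) of the cell cycle and Blm (1.68 ± 0.24) and Brca2 (1.51 ± 0.20) fell less in B10.BR, and Jhy (5.87 ± 0.40), whose probe was not examined for strain variants, had the largest positive difference among named genes above background in every group. The change was lower in B10.BR for Hbb-bt (-3.83 ± 0.45) of red cells, Cd209a (-2.99 ± 0.18) and Clec10a (-1.54 ± 0.18) of dendritic cells, Lef1 (-1.18 ± 0.21) and Cd8b1 (-0.99 ± 0.18) of T cells, Mx2 (-1.63 ± 0.24) and Oas2 (-1.49 ± 0.30) of the interferon response and Mzb1 (-1.04 ± 0.14). It was higher for Ncr1 (1.39 ± 0.24) and Klrb1c (1.29 ± 0.22) of natural killer cells, Nqo1 (1.61 ± 0.15) and Ccng1 (0.75 ± 0.18). In all, 3757 of 29521 features passed, 2010 higher and 1747 lower, 1356 of them at least 2-fold. Of 36 proliferation genes 34 had a higher change in B10.BR, 0 a lower one and 2 did not pass (median 1.19, 1.17 with the block, adjusted p = 6.10e-29, or 0.0925 with estimated correlation). Of 27 T cell genes 0 had a higher change in B10.BR, 8 a lower one and 19 did not pass (0 and 9 over the list alone, median -0.40, -0.46 with the block, adjusted p = 1.41e-04, or 0.355 with estimated correlation). Of 20 dendritic cell genes 1 had a higher change in B10.BR, 7 a lower one and 12 did not pass (2 and 10 over the list alone, median -0.41, -0.12 with the block, adjusted p = 1.24e-05, or 0.0520 with estimated correlation). The interferon response list (33 genes, 2 and 14 over the list alone, median -0.40, 0.098 with the block, adjusted p = 1.25e-04, or 0.645 with estimated correlation) had 0 with a higher change in B10.BR, 10 with a lower one and 23 not passing. The interferon response call ended with slide as a block (adjusted p = 0.287), ranging from 3.01e-10 to 0.645 over all settings. Of 19 exocrine pancreas genes 0 had a higher change in B10.BR, 0 a lower one and 19 did not pass (median 4.79, -5.66 with the block, passing in that direction, adjusted p = 2.95e-04, or 0.645 with estimated correlation). Differences lost their call for 8 genes with spike-in scaling, 13 genes with slide as a block and Ccng1 and Oas2 with slide as a random block. The number of differences was 475 with spike-in scaling, 6390 with array weights, 408 with slide as a block and 1494 with slide as a random block.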

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

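The tests of irradiation as the source of the exocrine signal, of the sex mix of the pools and of Xist were chosen only after the result was seen.

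The 2 strains differed in their response to 300 cGy, by the limma test of the difference (change in B10.BR minus change in BALB.K, log2), for 3217 features. The medians of lists with a passing difference were proliferation 1.5, DNA repair 0.34, neutrophil and granulocyte precursor 0.48, megakaryocyte and platelet 0.38, oxidative stress response 0.27 and exocrine pancreas 4.75 on the higher side, and p53 targets -0.33, B cell -0.22, plasma cell -0.36, T cell -0.44, dendritic cell -0.40, stroma and endothelium -0.21, antigen presentation -0.32 and immediate early and heat shock -0.60 on the lower side. With an estimated correlation none of these lists passed (adjusted p of 0.0507 or more). Spike-in scaling moved every gene by 0.42, and of the lower side only T cell and immediate early and heat shock kept a negative median. Among the named genes the change in B10.BR was higher for Nxpe4 3.62, Mst1r 3.49, Ttk 2.28, Nusap1 2.08, Prc1 1.93, Brca1 2.20, Blm 1.54, Rad54l 1.53, Gclc 1.04, Nqo1 1.02 and Mki67 1.41. It was lower for Pnp2 -3.02, Ly6d -1.17, Cr2 -0.83, Pdia4 -0.93, Mzb1 -0.79, Lef1 -1.27, Cd3d -0.97, Cd209a -1.39, Clec10a -1.05 and Nr4a1 -1.44. Of 22 named genes, 9 calls ended with spike-in scaling and 2 with slide as a block.

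At 900 cGy in B10.BR against 800 cGy in BALB.K the responses differed too, by the same limma test, for 3757 features. The medians of lists with a passing difference were proliferation 1.19, DNA repair 0.31, NK and cytotoxic cell 0.34, oxidative stress response 0.16 and exocrine pancreas 4.79 on the higher side, and erythroid -0.22, plasma cell -0.45, T cell -0.40, regulatory T cell -0.29, dendritic cell -0.41, interferon response -0.40, antigen presentation -0.35 and immediate early and heat shock -0.75 on the lower side. With an estimated correlation none of these lists passed (adjusted p of 0.0520 or more). With slide as a block the exocrine list passed in the other direction, at -5.66, and the interferon list was at 0.098, not passing. The erythroid list, not passing, was at 0.41 with normexp background correction and 0.022 with only probes above background on every array. Among the named genes the change in B10.BR was higher for Jhy 5.87, Cdc6 1.88, Nusap1 1.77, Blm 1.68, Brca2 1.51, Ncr1 1.39, Klrb1c 1.29, Nqo1 1.61, Ccng1 0.75 and Mki67 1.07. It was lower for Hbb-bt -3.83, Mzb1 -1.04, Lef1 -1.18, Cd8b1 -0.99, Cd209a -2.99, Clec10a -1.54, Mx2 -1.63 and Oas2 -1.49. Calls ended for 13 of 18 named genes with slide as a block, which left 408 features, and for 8 with spike-in scaling. The probe of Jhy was not examined for strain variants.

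The mean level of the exocrine pancreas list ranged over 10.76 log2 between arrays. A response of the spleen to irradiation alone is argued against by 4 of 18 irradiated arrays that lay at or below the highest unirradiated array of their strain. Pancreas tissue taken along with the spleens may be the source, which the islet genes Ins1, Ins2, Sst, Iapp, Pyy and Chga were to test. Over 24 arrays their group-centred mean went with the exocrine mean at a Pearson's r of 0.298 (permutation p = 0.388) and a Spearman's rho of 0.0887 (permutation p = 0.731), with r = 0.358 without the 2 arrays farthest from the median. The value set beforehand as speaking against the explanation was an r under 0.3, but leaving out 1 array moved r from 0.121 (without BALB.K 300 cGy replicate 1) to 0.358 (without BALB.K 0 cGy replicate 1), so that pancreas tissue stays open. On BALB.K 300 cGy replicate 1, the array with the highest exocrine mean, Ins1 was at 1.08 and Ins2 at 1.09 log2, their highest over the 24 arrays.

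Proliferation genes fell less in B10.BR than in BALB.K at 300 cGy, with a median difference of 1.5 log2 (adjusted p = 0.0507 with an estimated correlation, camera). With spike-in scaling it was 1.92, which argues against array scaling as the whole cause. With slide as a block it was 1.74, a value set beforehand as speaking against slide, but it rests on 1 BALB.K array at 300 cGy, so that slide and strain cannot be told apart. For the sex mix of the pools a covariate could not decide, and over the 18 arrays with Y-linked signal the difference was 1.63. BALB.K then has 1 array at 0 and 1 at 300 cGy, so that sex mix and strain cannot be told apart for these genes. A difference between the strains may remain as a hypothesis, and the lower unirradiated level of these genes in B10.BR was not tested as its source.

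Y-linked genes were well above background on 6 of 12 BALB.K arrays and on all 12 B10.BR arrays. The lowest Xist level of the 6 BALB.K arrays without Y-linked signal lay 0.35 log2 above the highest of the 6 with it, so that pools of animals of different sex may be the source. B10.BR material on the irradiated BALB.K arrays is argued against by 11 genes that differ between the strains, whose median position between BALB.K without the signal (0) and B10.BR (1), all irradiated, was 0.0171 on the 5 BALB.K arrays with it (-0.0979 to 0.574). The unirradiated array with the signal was not tested. All 3 BALB.K arrays at 800 cGy had the signal, against 1 of 3 at the other doses, so that part of that contrast may be one of sex.

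Splits of the 6 arrays of a comparison number 10, 1 of them the real one, too few for a share under 0.05. The real count and the highest other were BALB.K 300 cGy 13812 and 651, BALB.K 400 cGy 15211 and 2, BALB.K 800 cGy 17240 and 1, B10.BR 300 cGy 12328 and 1, B10.BR 500 cGy 14413 and 1 and B10.BR 900 cGy 16001 and 1. Between doses they were BALB.K 400 vs 300 cGy 1410 and 39, BALB.K 800 vs 400 cGy 5500 and 3, B10.BR 500 vs 300 cGy 474 and 136 and B10.BR 900 vs 500 cGy 1355 and 1, and for the strains without irradiation 15760 and 102. For the 2 differences between strains 11 of 100 splits, the real one included, gave as many features, so that chance is not excluded by this count (real 3217 and 3757, highest other 16144 and 19491). In each split above the real count, 4 or 6 of the 6 arrays of 1 strain had their own dose and 0 or 2 of the other strain's, which turns part of the shared response to irradiation into a difference, a structure of the arrays.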

How the results depend on the processing

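The exocrine level or Y-linked signal as a covariate, BALB.K arrays with or without Y-linked signal alone and comparisons within 1 slide were chosen only after the data were seen.

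Counts of features that passed are those of limma at an adjusted p of 0.05, and a count within 1.5 times the reported one counts as the same, as does a change of sign where neither value is called. The cause of the moves below was not tested, except that fewer arrays in the fit leave fewer degrees of freedom. Median scaling gave 5167 for BALB.K 400 against 300 and 5207 for the strain difference at 300 cGy. Spike-in scaling gave 7955 for BALB.K 300 against 0, 9770 for BALB.K 400 against 0, 7268 for B10.BR 300 against 0, 8917 for B10.BR 500 against 0 and 784 for BALB.K 400 against 300. It also gave 1650 for BALB.K 800 against 400, 3 for B10.BR 500 against 300, 34 for B10.BR 900 against 500, 1578 for the strain difference at 300 cGy, 475 for the highest-dose strain difference and 3835 for the calls shared at 300 cGy. With only the arrays compared in the fit there were 8177 for BALB.K 300 against 0, 2 for BALB.K 400 against 300, 0 for B10.BR 500 against 300, 147 for B10.BR 900 against 500 and 873 for the strain difference at 300 cGy, the 0 standing beside 3614 features at an unadjusted p under 0.05. Array weights gave 3808 for BALB.K 400 against 300, 13487 for BALB.K 800 against 400, 3671 for B10.BR 500 against 300, 3105 for B10.BR 900 against 500 and 6390 for the highest-dose strain difference. With slide as a fixed block there were 2176 for BALB.K 400 against 300, 952 for B10.BR 500 against 300, 723 for B10.BR 900 against 500, 5743 for the unirradiated strains and 408 for the highest-dose strain difference, and with a random block 1494 for the highest-dose strain difference. Within 1 slide the counts of the first 3 of these were the same numbers. The exocrine level as a covariate gave 616 for BALB.K 400 against 300, 221 for B10.BR 500 against 300 and 487 for B10.BR 900 against 500. Y-linked signal as a covariate gave 804 for B10.BR 500 against 300 and only BALB.K arrays with Y-linked signal 1917 for BALB.K 800 against 400. The number of list tests that passed, 194, was 72 with an estimated correlation.

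The replicate number as a block gave 892 features for B10.BR 500 against 300, a comparison whose arrays do not pair, and no other count moved with that block.

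Leaving out 1 array at a time gave ranges of 11911 to 14550 for BALB.K 300 against 0, 13527 to 14871 for BALB.K 400 against 0, 15710 to 17042 for BALB.K 800 against 0, 254 to 2184 for BALB.K 400 against 300 and 3175 to 4793 for BALB.K 800 against 400. In B10.BR they were 10474 to 11419 at 300, 12988 to 13601 at 500 and 14596 to 15167 at 900 against 0. Between its doses they were 132 to 799 for 500 against 300 and 540 to 1263 for 900 against 500. They were 13472 to 16264 for the unirradiated strains, 1893 to 4753 for the strain difference at 300 cGy and 2573 to 4795 for the highest-dose strain difference, and 189 to 199 list tests. Single arrays moved some counts by over 1.5 times. BALB.K 400 against 300 counted 2184, 287 and 254 without 300 cGy replicates 1, 2 and 3 in turn. It counted 435, 289 and 279 without 400 cGy replicates 1, 2 and 3. BALB.K 800 against 400 counted 3259 and 3467 without 400 cGy replicates 2 and 3 in turn and 3175 without 800 cGy replicate 2. The strain difference at 300 cGy counted 1893 without B10.BR 0 cGy replicate 3. B10.BR 500 against 300 counted 199 and 220 without 300 cGy replicates 2 and 3. It counted 132, 161 and 799 without 500 cGy replicates 1, 2 and 3. B10.BR 900 against 500 counted 900 and 725 without 500 cGy replicates 1 and 2. It counted 773 and 540 without 900 cGy replicates 1 and 3.

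Directions turned as follows, and the cause was not tested. With spike-in scaling, Cdkn1a was at -0.27 for the unirradiated strains and Trp53 was at 0.037 for B10.BR 300 against 0. With the mean of all probes of a gene, Cdkn1a was at -0.48 for the unirradiated strains and 1.24 for the strain difference at 300 cGy. For the highest-dose strain difference, the erythroid list was at 0.41 with normexp background correction and 0.022 with only probes above background on every array. With slide as a block, the interferon response list was there at 0.098 and the exocrine pancreas list at -5.66. Of the gene values only the 2 with the mean of all probes passed, and of the list values only the -5.66. The exocrine level as a covariate is the mean of the exocrine list, so that it fixes that list's change near 0, and its values of -0.11 for BALB.K 800 against 0, -0.15 for B10.BR 900 against 0, 0.015 for B10.BR 500 against 300, -0.14 for B10.BR 900 against 500, -0.056 for the strain difference at 300 cGy and -0.19 for the highest-dose strain difference say nothing on stability. For lists the value is the median, and the direction is that of camera.

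Of the named genes and passing lists, those that kept direction and side of the threshold were 288 of 289 genes and 186 of 194 lists with quantile normalization, 284 of 289 genes and 191 of 194 lists with median scaling, 229 of 289 genes and 183 of 194 lists with spike-in scaling and 288 of 289 genes and 190 of 194 lists with normexp background correction. They were 250 of 289 genes with only the arrays compared, 263 of 289 genes and 179 of 194 lists with slide as a block, 265 of 266 genes with the deposited matrix, 271 of 284 genes and 173 of 184 lists with the exocrine level as a covariate and 285 of 289 genes and 187 of 194 lists with Y-linked signal as a covariate, the exocrine genes and list being left out for the exocrine level. For the other settings run on all of them they were 285 of 289 genes and 185 of 194 lists or more. Over the single arrays left out, 1916 of 1974 gene values did. With fry 166 of the 194 lists did, and with an estimated correlation 72. The others mostly kept direction and lost the call. Signal over background limits the changes of genes near or below background in a group, which are given as bounds.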

Other observations

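The principal components and the agreement of replicates were computed as a description and test no hypothesis.

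The first principal component of all features held 39.4% of the variance and the second 28.9%. All 12 BALB.K arrays lay below 0 on the first and all 12 B10.BR arrays above it. On the second, the 6 unirradiated arrays lay between 85.3 and 115, the 300 cGy arrays between -30.8 and 5.81, the 800 cGy arrays between -78.9 and -74.8 and the 900 cGy arrays between -52.5 and -47.5. Arrays of 1 group correlated across genes, which are not independent replicates, at 0.972 to 0.996. The median standard deviation of a feature within a group was highest in unirradiated BALB.K (0.22 log2, n = 3) and lowest in BALB.K at 800 cGy (0.11 log2, n = 3).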
